A study of Drosophila melanogaster with 3 samples.

How the data were processed

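Gene expression was measured in wings of *Drosophila melanogaster* pupae of the Oregon R strain at about 80 h after puparium formation (APF), with 3 biological replicates on 1 Affymetrix array each. Per the labels' protocols, flies were kept at 25 C, wings were dissected from the pupal case after the surrounding membrane was removed, RNA came from batches of 40 flies, and biotinylated cRNA was made from 5 ug of total RNA. Staging was by eye from wing pigmentation, so the age is approximate. All 3 arrays belonged to a single group, and no contrast between conditions existed in the design.

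The deposited values were probe set signals on a linear intensity scale for 18952 probe sets. Per the submitters' processing notes, MAS5 and RMA were used, with no role, order or version given for either. The values themselves had a trimmed mean of 500.0 on every array after 2% was removed at each end, and they were linear with a spread that grew steeply towards low signals, which are features of MAS5 signals. The genome build and the annotation behind the probe sets are not given in the sources used here. The signals were used as log2 values without further normalization, since all arrays already shared 1 scale.

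Probe sets were named through the platform annotation. A single gene symbol was given for 13646 probe sets, several symbols for 402 and none for 4721, beside 183 control probe sets. The entrez identifiers of 13543 probe sets were found in the RefSeq gene table, and no symbol needed to be changed. Probe sets with several symbols named no gene. Each of the resulting 11981 genes took its probe set with the highest mean over the arrays, which was a choice among several probe sets for 1094 genes. The order of signals between probe sets depends on the probes as well as on the transcript and is not an order of transcript abundance.

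A gene was called above the reference by comparison with genes whose products belong to antennae, ovary or male accessory gland. This negative reference held 83 measured genes, of which 56 were odorant receptors and 27 were eggshell or accessory gland proteins. The reference level of an array was the 95th percentile of these genes. limma 3.58.1 in R 4.3.3 (lmFit, eBayes) was applied to each gene's log2 signal minus the reference level of the same array. The one-sided moderated test asked whether the mean difference exceeded 0, with Benjamini-Hochberg adjustment over the 11981 genes and a threshold of 0.05. The prior had 1.5 degrees of freedom and an SD of 0.319. The uncertainty of the reference level was taken from 2000 bootstrap resamples of the 83 genes, which the test itself does not include.

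Gene lists were fixed before the data were examined. They covered transcription factors in 5 families (homeodomain, bHLH, nuclear receptor, zinc finger C2H2 or BTB, and other families), wing patterning regulators, head, posterior and early embryonic regulators, pigment and sclerotisation enzymes, eye pigment genes, adult cuticle proteins, larval and prepupal cuticle proteins, Tweedle proteins, chitin synthesis and modification, zona pellucida domain proteins of the apical matrix, planar polarity and wing hair, ecdysone response, signalling, and integrins and cell-matrix adhesion. Further lists held markers of neurons, glia, muscle, fat body, haemocytes, trachea, photoreceptors, testis, germ line and midgut, and genes of the sex-biased, Y-linked, cell cycle, apoptosis, circadian clock, antimicrobial, heat shock and ribosomal groups. Of 1136 list entries 914 were measured, 18 had only probe sets shared with another gene, and 204 were not analysed here. The zona pellucida list contains trn, which encodes a leucine-rich repeat protein, and the integrin list contains tsl, which belongs to embryonic terminal patterning. Both lists were used as fixed. The share of each of the 37 lists with a measured size of at least 3 was set against all other named genes outside the negative reference with a 2-sided Fisher's exact test in scipy 1.17.1, adjusted by Benjamini-Hochberg over the 37 lists. Genes within a list are not independent of each other, so these p-values describe the lists and not replicate variation. Fisher tests between 4 pairs of lists were chosen after the shares were known.

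Agreement between arrays was described by Pearson's r across genes, the SD of log2 differences and each gene's SD, with no test, because genes are not replicates. Agreement across genes chosen by their mean alone was added after the values of the called genes were seen. For each list with at least 5 members above the reference, the median deviation of an array from the genes' means was ranked among 10000 random lists of the same size drawn from genes of like mean signal, 50 on each side, and the central 95% was taken as the range of random lists. The SD limit of 0.5 for variable genes was set after the values were seen. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

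Genes named in the text followed a rule fixed before the data were examined: the first 8 measured members of each list, the 20 transcription factors with the highest mean among those above the reference, the 10 transcription factors and 10 genes with the largest SD among those above it, and the 10 genes with the highest mean. Genes outside this rule were named after their values were seen: the remaining called members of small counts, namely Ccp84Ae, TwdlH, TwdlK, bol, Mst36Fa, twe, BicD, dpa, CycD, ninaD, rdgA, rdgB, rdgC, Ppn, PGRP-LB and PGRP-LE, and single members of interest, namely Mmp2, yellow-b, yellow-d2, yellow-e, yellow-h, amd, PPO1, PPO2, PPO3, aop, sls, Strn-Mlck, Mlp84B, Snap25, nompA, Cht7, Idgf2, da, ImpL2 and sn.

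The test was also run on simulated arrays whose means and spreads were taken from these data. A first simulation held all other genes at or below the reference and lifted 200 of 11981 genes by 1, 1.5 or 2 on the log2 scale. It recovered 0 of 200 after adjustment, although all 200 had an unadjusted p below 0.05, so with 3 arrays the test has little power when few genes are above the reference. A second simulation was added after that result and kept every other gene at its real mean, as in these data. It recovered 26 of 50 genes lifted by 0.5, 49 of 50 lifted by 1, and 50 of 50 at both 1.5 and 2, with 4 false calls among 5612. The recovery therefore holds for a tissue in which many genes are above the reference. Simulated genes of like mean signal all had the same SD, so it does not cover genes with a larger spread of their own. In these data aop, for example, lay 2.31 over the reference and was not called. In the second simulation the reference level was taken as known, so its false calls do not cover an error in that level. Such an error would be shared by all genes, and its effect on false calls was not tested.

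The alternatives tried were the 99th percentile or the median plus 1 as the reference level, each negative list alone, quantile normalization, median centring, the mean of a gene's probe sets, removal of probe sets that can hybridise to more than 1 transcript, a call from all 3 arrays without a model, limma with an intensity trend, and leaving out each replicate in turn. The probe sets removed for possible hybridisation to several transcripts were those with the suffix _s_at or _x_at. All carried a single gene symbol, so signal from another gene was not shown. A reference made of 29 non-fly control probe sets was added after the data were seen. The number of arrays limits the precision of every value.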

Results

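Wings of Oregon R pupae at about 80 h APF, a stage when the adult wing cuticle is laid down and pigmented, were profiled on 3 arrays from 3 biological replicates. The aim stated for the series was to profile transcription factors. The median probe set signal was 67.6, 73.3 and 59.7 on replicates 1, 2 and 3, and the reference level set by genes of other organs was 93.3, 105.8 and 96.1. Values are given as mean log2 signal ± SD over the 3 arrays. Genes are described as above or not above the reference, because the order of signals between probe sets is not an order of transcript abundance. The highest signals named below served only to choose genes to name.

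The late pupal wing carried signal above the reference for 5531 of 11981 named genes (46.2%). Of these, 4977 lay at least 2-fold over it. The 10 genes with the highest mean signals included the cytoplasmic myosin light chain Mlc-c (15.87 ± 0.04, n = 3), the actin-binding protein gene cib (15.55 ± 0.07), the aquaporin gene Prip (15.58 ± 0.09), the cuticle protein gene Cpr64Aa (15.57 ± 0.20), and CG14961, CG34417, CG17298, Vajk2, Jhbp13 and CG15674. All 28 measured cytoplasmic ribosomal protein genes were above the reference, against 46.4% of other genes (Fisher's exact test, adjusted p = 1.73e-08), with RpLP0 at 14.12 ± 0.04 and RpL15 at 15.19 ± 0.14. None of the 83 reference genes was called by limma, and 1 had an unadjusted p below 0.05, a result partly set by the way the level is defined. At an unadjusted p below 0.05 the number of genes above the reference was 5696. Bootstrap intervals of the reference level ran from 84.1 to 144.3, from 86.4 to 150.1 and from 70.5 to 130.8 on the 3 arrays, so genes close to it are uncertain.

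Transcription factors were the purpose of the series, and 123 of 302 measured members were above the reference (40.7%, against 46.6% of other genes; Fisher's exact test, adjusted p = 0.115). The same count was reached when adjusted over the list alone. The factors with the highest signals included crc, the fly ATF4 (14.96 ± 0.06), grh, a regulator of epidermal barrier genes (14.02 ± 0.08), the zinc finger genes jim (13.37 ± 0.08) and cbt (13.27 ± 0.07), the HLH gene emc (13.16 ± 0.06), and kay, the fly Fos (13.07 ± 0.15). Further members of this set were salm, nub, noc, ovo, ap, ken, tx, tgo, Atf3, gem, ftz-f1, Hr39, Hr78 and cnc. The call of cnc rested on a probe set that can hybridise to more than 1 transcript, and without such probe sets cnc lay at -3.23 and Hr39 at -0.26 against the reference. With the mean of each gene's probe sets, 37.4% of the factors were above the reference and the lower share passed the threshold (adjusted p = 0.0334).

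Homeodomain genes had a lower share than the other families. Most head, posterior and early embryonic regulators are also in the homeodomain list, so the low shares of these lists are not independent results. Of 77 measured members 18 were above the reference (23.4%; Fisher's exact test, adjusted p = 0.000413), among them ap, nub, Dll, en, inv, al, pdm2 and vvl. Among the other transcription factors 105 of 225 were above (46.7%), and the difference between these shares, tested after they were known, gave a p of 0.000285 by Fisher's exact test. Of bHLH genes 20 of 51 were above the reference (adjusted p = 0.526). The proneural genes ac (4.64 ± 1.80), sc (4.80 ± 0.89), ase (5.34 ± 0.89) and ato (5.50 ± 0.70) were not, whereas their general partner da was at 11.33 ± 0.09. Nuclear receptors were above in 9 of 20 cases (adjusted p = 1.0), zinc finger and BTB genes in 35 of 68 (adjusted p = 0.688) and members of other families in 41 of 86 (adjusted p = 0.959), a count that was 42 when adjusted over the list alone.

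Regulators of the head, the posterior body and the early embryo were not above the reference, whereas many of those that pattern the wing were. Of 32 wing patterning regulators 20 were above (62.5%), including salm (12.98 ± 0.04, n = 3; limma adjusted p = 8.2e-05), the dorsal selector ap (11.40 ± 0.26), bs, which encodes the fly SRF (11.22 ± 0.05), Dll (9.89 ± 0.24), the posterior selector en (9.74 ± 0.11), the wing selector vg (9.61 ± 0.14) and bi (9.58 ± 0.02). The paralog of salm, salr, was not called (6.81 ± 0.61; limma adjusted p = 0.589). Of 24 head, posterior and embryonic regulators 0 were above, and 0 had an unadjusted limma p below 0.05. Examples were Scr (3.23 ± 1.51), ey (3.55 ± 0.72), bcd (3.64 ± 1.19), Dfd (4.11 ± 0.97) and pb (2.90 ± 0.42). The share of this list was lower than that of other genes (Fisher's exact test, adjusted p = 7.26e-06), whereas the share of the wing list was not past the threshold (adjusted p = 0.178). The shares of both lists differed from each other in a Fisher's exact test chosen after they were seen (p = 3.74e-07). The wing list count was 22 when adjusted over the list alone. The wing share was 50% with the mean of probe sets (adjusted p = 0.849), where kn (7.97 ± 0.33) lay at -0.25 against the reference. It was 55.2% without _s_at and _x_at probe sets (adjusted p = 0.411).

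**Figure D1:**
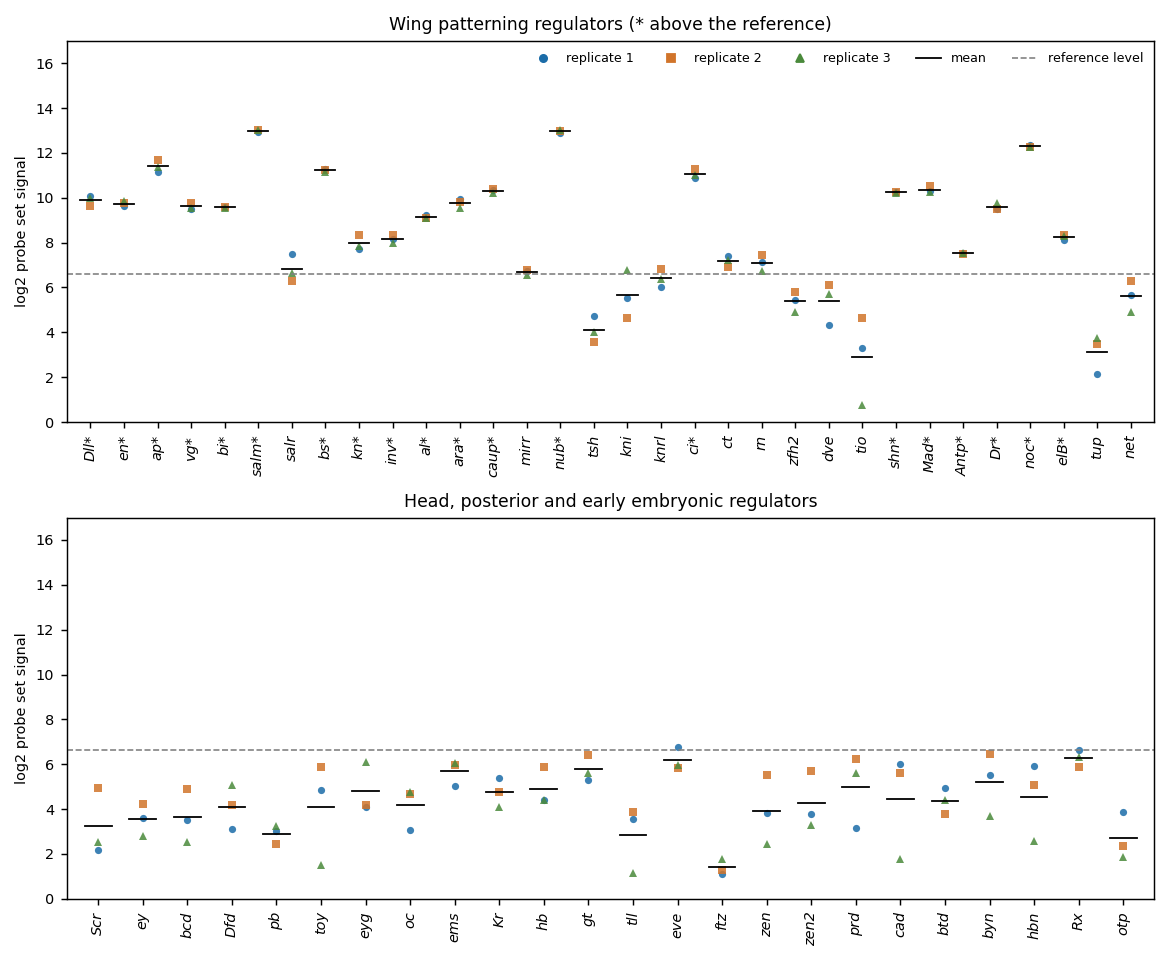
Log2 probe set signal of wing patterning regulators (top) and of head, posterior and early embryonic regulators (bottom) on the 3 arrays, with the mean as a bar and the mean reference level as a dashed line. Of the wing regulators 20 of 32 carry an asterisk for a call above the reference, and 0 of 24 in the lower panel.

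Of 26 genes for pigment and sclerotisation enzymes 12 were above the reference (46.2%, against 46.5% of other genes; Fisher's exact test, adjusted p = 1.0). Above it were ple, tyrosine hydroxylase (11.33 ± 0.20, n = 3), Ddc, dopa decarboxylase (14.30 ± 0.10), y (10.29 ± 0.18), t, which releases dopamine from its beta-alanine conjugate (13.23 ± 0.12), e, which makes that conjugate (11.97 ± 1.18), stw, a laccase (14.28 ± 0.15), and Pu, GTP cyclohydrolase (12.44 ± 0.39). The related genes yellow-b, yellow-d2, yellow-e and yellow-h were above it too, at 14.29 ± 0.04, 12.12 ± 0.16, 14.30 ± 0.13 and 12.62 ± 0.15. Not above were speck (4.48 ± 0.48), amd (3.10 ± 0.52) and the prophenoloxidases PPO1 (3.57 ± 0.52), PPO2 (6.82 ± 0.74) and PPO3 (2.94 ± 0.93). Eye pigment genes were above it in 11 of 16 cases (adjusted p = 0.181), with pr (10.35 ± 0.20), cl (10.52 ± 0.24) and ry (9.58 ± 0.22) among them. The genes cn (3.18 ± 1.62), st (4.61 ± 1.43), bw (5.39 ± 0.89), cd (3.48 ± 1.63) and se (5.99 ± 0.94) were not.

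Adult cuticle protein genes were above the reference more often than larval and Tweedle genes. Of 36 adult cuticle protein genes 22 were above the reference (61.1%; Fisher's exact test, adjusted p = 0.191), with Cpr64Aa, Cpr64Ac (15.31 ± 0.13, n = 3) and Acp65Aa (13.74 ± 0.14) among them and Cpr47Ea (4.44 ± 0.72) and Cpr49Aa (1.87 ± 0.97) not. Of 13 larval and prepupal genes only Ccp84Ae (8.38 ± 0.19) was above (7.69%; adjusted p = 0.0179). Edg78E (6.47 ± 0.92), Edg84A (5.15 ± 1.95), Pcp (5.52 ± 0.98) and Lcp9 (4.94 ± 0.59) were not, and Lcp65Aa (7.17 ± 0.40) passed only in some settings, such as without replicate 2 (0.83 over the reference). Of 25 Tweedle genes TwdlT (11.32 ± 0.25), TwdlE (10.65 ± 0.13), TwdlK (7.87 ± 0.29) and TwdlH (7.35 ± 0.23) were above (16%; adjusted p = 0.00963), TwdlH not without replicate 1 (0.74 over the reference). Adult and larval shares differed with a p of 0.00102, and adult and Tweedle shares with a p of 0.000574, both by Fisher's exact tests chosen after the shares were seen. The larval call was lost without replicate 2 (23.1%, adjusted p = 0.319) and under 3 other reference levels and the limma intensity trend, with adjusted p from 0.0681 to 0.223.

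**Figure D2:**
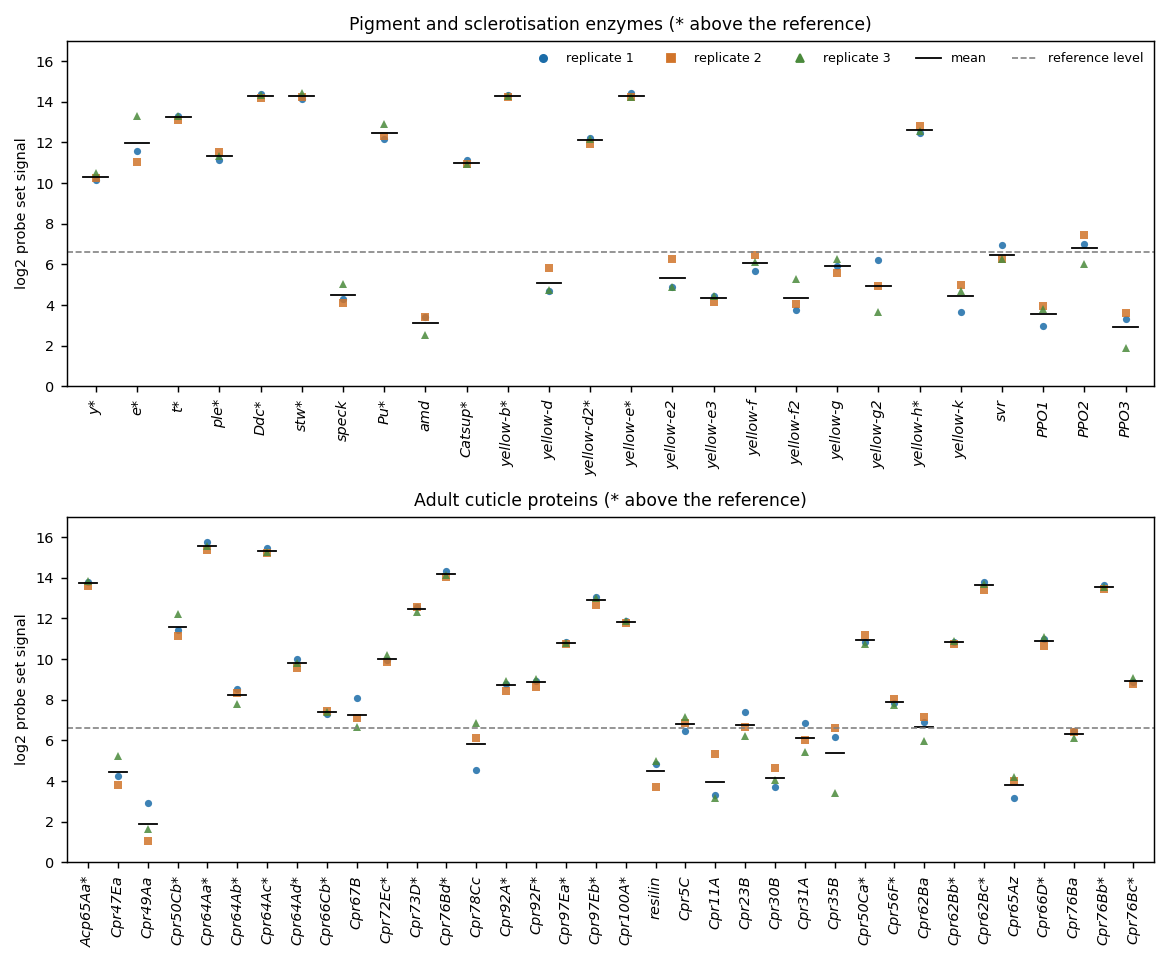
Log2 probe set signal of pigment and sclerotisation enzymes (top) and adult cuticle proteins (bottom) on the 3 arrays, with the mean as a bar and the mean reference level as a dashed line. Asterisks mark the 12 of 26 and 22 of 36 genes above the reference, and e shows replicate 3 at 13.30 against 11.59 and 11.02.

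Of 28 chitin genes 19 were above the reference (67.9%; Fisher's exact test, adjusted p = 0.0996), among them the chitin synthase kkv (10.82 ± 0.21, n = 3), knk (8.98 ± 0.17), the deacetylases serp (10.51 ± 0.45) and verm (10.31 ± 0.34), the chitinase family member Cht7 (14.40 ± 0.11) and Idgf2 (14.75 ± 0.11). The gut chitin synthase Chs2 was not (5.36 ± 0.72). Of 12 zona pellucida domain genes 7 were above (adjusted p = 0.732), with pio (14.77 ± 0.15), dpy (10.11 ± 0.47) and neo (7.70 ± 0.27) among them, whereas dy (4.66 ± 1.44) and dyl (5.02 ± 1.48) were not. The zona pellucida share was 33.3% with the 99th percentile as reference and 41.7% with eggshell and accessory gland genes alone. The chitin share passed the threshold with the 99th percentile as reference (64.3%, adjusted p = 0.0427) and without probe sets that can hybridise to more than 1 transcript (69.2%, adjusted p = 0.0329).

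Planar polarity and wing hair genes and integrin and matrix genes had higher shares than other genes. In each list 14 of 15 measured members were above the reference (93.3%; Fisher's exact test, adjusted p = 0.00142). The polarity genes included Vang (10.60 ± 0.19, n = 3), ds (10.28 ± 0.26), mwh (9.92 ± 0.22), dgo (9.23 ± 0.08) and stan (7.65 ± 0.25), with the actin bundler gene sn at 9.18 ± 0.03, and the exception was in (6.62 ± 0.17). With the mean of its probe sets mwh was not called (0.09 over the reference, adjusted p = 0.854). The adhesion genes included the integrin subunits mys (13.76 ± 0.23), if (13.14 ± 0.09) and mew (9.96 ± 0.06), talin, encoded by rhea (13.09 ± 0.08), and Ilk (13.68 ± 0.14), and the exception was Mmp2 (5.64 ± 0.70). The polarity call was lost with the 99th percentile as reference (66.7%, adjusted p = 0.141) and with eggshell and accessory gland genes alone as reference (73.3%, adjusted p = 0.0594).

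Ecdysone response genes split among their members, with 14 of 24 above the reference (58.3%; Fisher's exact test, adjusted p = 0.526). The receptor genes EcR (10.69 ± 0.09, n = 3) and usp (8.84 ± 0.06), the late prepupal regulator ftz-f1 (12.32 ± 0.10), Hr39 (12.07 ± 0.11), Hr3 (8.92 ± 0.13) and the secreted insulin antagonist gene ImpL2 (12.74 ± 0.16) were above, and Hr4 (5.58 ± 0.43), Eip78C (7.09 ± 0.58) and Hr38 (6.69 ± 0.86) were not. Eip78C was, however, over the reference on all 3 arrays and passed with the median plus 1 (limma adjusted p = 0.0187) and non-fly controls (adjusted p = 0.0276) as reference. With the median plus 1 the adjusted p of gained calls followed the difference and not the gene's SD, so more than the level changed. br was above the reference at 7.81 ± 0.17 but lay at -0.04 against it with the mean of its probe sets. Of 18 signalling genes 12 were above (66.7%; adjusted p = 0.191), including tkv (12.92 ± 0.14), fng (12.04 ± 0.12), the bursicon receptor rk (10.32 ± 0.14), Egfr (9.04 ± 0.16) and dpp (7.89 ± 0.15), whereas hh (5.44 ± 0.81) was not.

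Markers of other cell types were present in part. Of 19 neuronal genes 10 were above the reference (Fisher's exact test, adjusted p = 0.775), among them Appl (8.52 ± 0.09, n = 3), Snap25 (9.65 ± 0.21) and nompA, a gene of sensory organ support cells (9.81 ± 0.21). The count was 12 when adjusted over the list alone, since elav (7.63 ± 0.71) and para (7.59 ± 0.75) were close to the threshold; elav passed without replicate 2 (1.39 over the reference) and para without replicate 3 (1.38). The neuronal share of 52.6% fell to 36.8% with the 99th percentile as reference and rose to 63.2% with the median plus 1. It was 42.1% with eggshell and accessory gland genes alone. It was also 42.1% with the mean of probe sets, where futsch lay at -1.17 and cac at -0.89. Of 9 glial genes 6 were above (adjusted p = 0.526), including repo (7.50 ± 0.28), moody (11.03 ± 0.34) and nrv2 (11.57 ± 0.16). The repo call was lost with the 99th percentile (0.24 over the reference) and with eggshell and accessory gland genes alone as reference (0.44). Muscle genes were above in 9 of 19 cases (adjusted p = 1.0), with Act88F at 8.93 ± 0.50, fln at 8.18 ± 0.51, sls at 13.32 ± 0.27 and Strn-Mlck at 14.07 ± 0.14, whereas TpnC4 (6.26 ± 0.12) and up (4.99 ± 1.19) were not. Fat body genes were above in 6 of 10 cases (adjusted p = 0.726), with Lsp2 at 8.88 ± 0.28 and apolpp at 9.36 ± 0.24 and the yolk protein genes Yp1, Yp2 and Yp3 not, at 3.41 ± 2.15, 3.12 ± 1.22 and 3.09 ± 0.11. Of 13 haemocyte genes crq (11.90 ± 0.17), NimC1 (7.68 ± 0.14), Ppn, vkg and Col4a1 were above (adjusted p = 0.732), while Hml (4.97 ± 1.18) and He (5.38 ± 1.67) were not. Of 10 tracheal genes 6 were above (adjusted p = 0.726), 4 of which (Gasp, serp, verm and pio) also stand in the chitin or zona pellucida lists, and btl (2.74 ± 1.12) was not.

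Midgut and testis genes had lower shares above the reference than other genes. None of 27 midgut protease and amylase genes was called by limma, with 0 at an unadjusted p below 0.05 (Fisher's exact test, adjusted p = 1.44e-06); alphaTry was at 3.88 ± 1.80 (n = 3) and Jon25Bi at 5.15 ± 1.46. Of 27 testis genes bol (8.36 ± 0.43), Mst36Fa (8.62 ± 0.25) and twe (7.46 ± 0.07) were above (11.1%; adjusted p = 0.00102), and Mst84Da (6.79 ± 0.48) and Mst87F (5.04 ± 1.62) were not. The bol call rested on a probe set that can hybridise to more than 1 transcript, and without such probe sets bol lay at -4.52. The testis share was 18.5% with the median plus 1 and 22.2% with non-fly controls as reference, and still lower than that of other genes (adjusted p = 0.00697 and 0.0152). Of 11 germ line genes only BicD (10.54 ± 0.21), which also acts in somatic transport, was above (adjusted p = 0.0512), with vas at 5.39 ± 0.37 and osk at 6.07 ± 0.15. This share passed the threshold in 4 alternative settings, with adjusted p from 0.0232 to 0.0481. Y-linked genes were above in 0 of 6 cases, with 0 at an unadjusted limma p below 0.05 (adjusted p = 0.0996), and the share was 16.7% with non-fly controls as reference. Of 14 photoreceptor genes ninaB (7.71 ± 0.34), ninaD, rdgA, rdgB and rdgC were above (adjusted p = 0.732), ninaD not without replicate 3 (0.69 over the reference), while trp (2.04 ± 1.10), inaD (2.31 ± 0.89) and Arr1 (3.46 ± 0.81) were not. Of 5 sex-biased genes Sxl (12.17 ± 0.12) and msl-2 (7.56 ± 0.33) were above (adjusted p = 1.0). With the 99th percentile, and with eggshell and accessory gland genes alone, the photoreceptor share was 21.4% instead of 35.7% and the sex-biased share 20% instead of 40%. The latter was 25% without _s_at and _x_at probe sets.

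Genes of the cell cycle were mostly not above the reference, and clock genes mostly were. Of 16 cell cycle genes CycE (7.30 ± 0.39, n = 3), CycD (7.64 ± 0.34) and dpa (7.23 ± 0.27) were above (18.8%; Fisher's exact test, adjusted p = 0.109), and 1 when adjusted over the list alone. The replication genes PCNA (4.81 ± 1.13), Mcm2 (6.48 ± 0.39) and Mcm5 (2.93 ± 0.80) and the mitotic cyclin genes CycB (5.86 ± 0.66) and CycB3 (5.52 ± 0.29) were not. The share depended on the reference and on how genes were called. It was 31.2% with the median plus 1 (adjusted p = 0.353) and with 3 arrays and no model (adjusted p = 0.355), 37.5% with non-fly controls (adjusted p = 0.524) and 0.0% with the 99th percentile (adjusted p = 0.00212). A lower share passed the threshold without replicate 1 (12.5%, adjusted p = 0.0422), without replicate 2 (6.25%, adjusted p = 0.00841) and without replicate 3 (6.25%, adjusted p = 0.00886), where fewer members were called; dpa was not called without any 1 replicate (0.45 to 0.69 over the reference). Of 8 clock genes 7 were above (adjusted p = 0.0973), with per at 7.91 ± 0.24, tim at 9.81 ± 0.20, Clk at 8.88 ± 0.50, cyc at 8.67 ± 0.22 and cwo at 10.62 ± 0.19, and the exception was the blue light receptor gene cry (5.09 ± 1.47). With the mean of probe sets tim was not called (0.31 over the reference, adjusted p = 0.241) and the clock share was 75% (adjusted p = 0.295). The clock share passed the threshold with the 99th percentile as reference (adjusted p = 0.0361) and with eggshell and accessory gland genes alone (adjusted p = 0.0435).

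Stress, immune and cell death genes showed mixed states among the members measured. These were only 6 of 18 listed heat shock genes, 10 of 21 antimicrobial genes and 6 of 10 apoptosis genes. Hsp83, all Hsp70 genes and the death inducers rpr and hid were not measured, so the counts do not cover them. Of 6 heat shock genes 5 were above the reference (Fisher's exact test, adjusted p = 0.191), namely Hsc70-4 (15.44 ± 0.05, n = 3), Hsc70-3 (11.71 ± 0.01), DnaJ-1 (11.94 ± 0.07), Hsp27 (8.06 ± 0.25) and Hsp26 (7.61 ± 0.22), and stress-induced Hsp68 was not (5.79 ± 0.40). Of 10 antimicrobial and peptidoglycan recognition genes Drs (10.47 ± 0.12), CecB (7.79 ± 0.14), PGRP-SC2 (8.74 ± 0.12), PGRP-LB (9.39 ± 0.04) and PGRP-LE (9.78 ± 0.18) were above (adjusted p = 1.0), and DptB (4.05 ± 0.33), Def (3.71 ± 0.93) and Mtk (4.90 ± 0.93) were not. Of 6 apoptosis genes Dark (12.98 ± 0.06), Dronc (12.95 ± 0.27), Diap2 (11.46 ± 0.14) and Dcp-1 (7.81 ± 0.39) were above (adjusted p = 0.657), and the death inducers grim (3.83 ± 1.14) and skl (4.02 ± 0.47) were not.

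Replicates differed little for genes with signals over the reference. Across the 5531 genes called by limma Pearson's r was 0.986, 0.986 and 0.983 for replicates 1 and 2, 1 and 3, and 2 and 3, and the SD of the log2 difference was 0.304, 0.309 and 0.346. The limma test favours genes with a small SD over the same arrays, which lowers these differences. Across the 6206 genes chosen by a mean over the reference alone, r was 0.983, 0.984 and 0.980 and the SD of the difference 0.356, 0.357 and 0.390. The median SD of the called genes over the arrays was 0.159. Over all 11981 named genes, the median SD was 0.088 for mean log2 signals of 13 to 17 and 1.09 for those of 0 to 5, so low signals were poorly determined. These are correlations across genes, which are not independent replicates. Over all named genes the mean SD of the difference was 1.11.

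Among the 10 genes above the reference with the largest SD over the arrays, 8 were highest on replicate 3. e was at 11.59, 11.02 and 13.30 on replicates 1, 2 and 3. CG9686 (SD 1.60), CG13606 (SD 1.53), CG7778 (SD 1.38), Jhbp11 (SD 1.12), CG13082 (SD 1.09), CG10550 (SD 1.07) and the carbonic anhydrase gene CAH1 (SD 1.06) also had their highest value on replicate 3, and CG13082 was not called without replicate 1 (1.91 over the reference). The non-coding lncRNA:alphagamma-element:CR32865 (SD 1.23) and 18SrRNA-Psi:CR41602 (SD 1.02) were highest on replicate 2, at 10.02 and 9.84, and the first of them was not called without replicate 3 (2.19 over the reference). Among the transcription factors called by limma the clock gene vri (9.65 ± 0.68, n = 3), the hormone response gene Kr-h1 (8.29 ± 0.53), Irbp18 (9.96 ± 0.51), Clk and Eip93F (10.61 ± 0.49) varied most. aop, which narrowly missed the threshold (adjusted p = 0.0526), had a larger SD of 1.72. An SD over 0.5 was seen in 140 called genes, of which 82 (58.6%) were highest on replicate 3, compared with 24.9% of all genes above the reference. Replicate 2 was the lowest array for 70 of the 140, e among them, against 33 for replicate 1 and 37 for replicate 3. The limit of 0.5 was chosen after the values were seen.

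**Figure D3:**
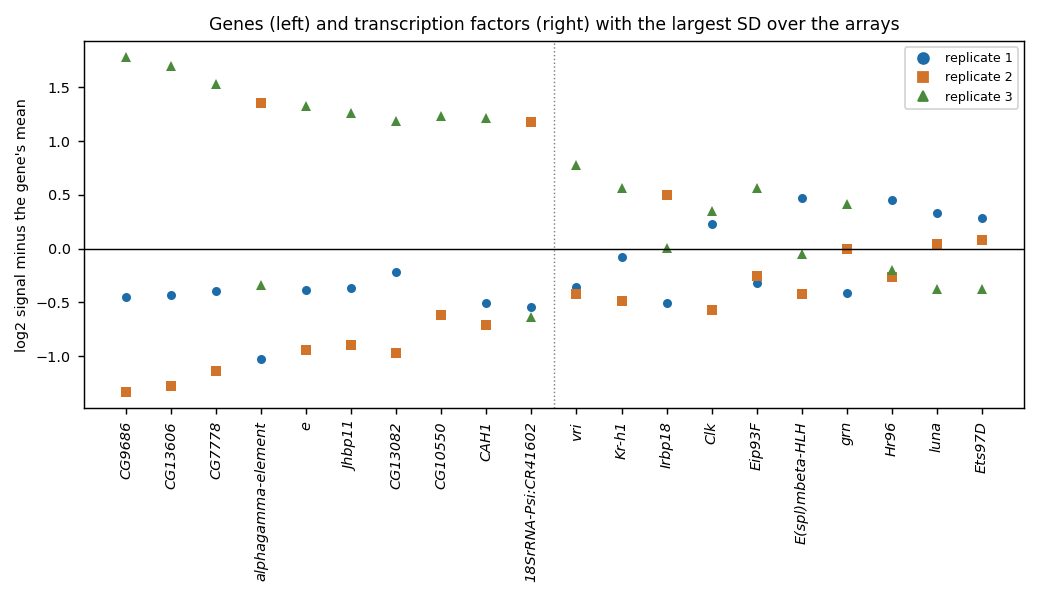
Log2 signal minus the gene's mean on each array for the 10 genes (left) and 10 transcription factors (right) above the reference with the largest SD. Replicate 3 is the highest array for e, CG9686, CG13606 and CG7778.

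Gene lists deviated between arrays by small amounts. On replicate 2 the median deviation was -0.13 for the 22 adult cuticle genes, -0.11 for the 19 chitin genes, -0.13 for the 7 zona pellucida domain genes, -0.16 for the 9 muscle and the 6 tracheal genes, -0.20 for the 7 clock genes and 0.12 for the 20 bHLH genes. On replicate 3 it was 0.11 for chitin and 0.10 for tracheal genes, and on replicate 1 it was -0.07 for bHLH genes, -0.09 for ecdysone response genes and -0.18 for the 5 photoreceptor genes. These 12 of 81 combinations of list and array fell outside the central 95% of random lists, where 4.0 would be outside by chance. Tracheal, chitin and zona pellucida lists share members and are not independent. Deviations are taken from the mean of the same 3 arrays, so a low value on 1 array raises those on the others. Members of a list can also vary together, which lists drawn at random do not reproduce. The combinations are therefore not separate chances. The number outside was 14 of 81 after quantile normalization, 12 of 81 after median centring and 12 of 111 over all measured members, where 5.5 would be outside by chance. Median centring shifts all genes of an array alike and brought the bHLH deviation on replicate 2 to -0.01. It was still outside the range of random lists (percentile 99.4). Over all measured members, replicate 2 was no longer outside the range for muscle (0.08, percentile 65.1), chitin (-0.06, percentile 5.56), zona pellucida (-0.08, percentile 5.78) and bHLH genes (0.17, percentile 93.4), nor replicate 1 for photoreceptor genes (-0.18, percentile 2.96). Chitin on replicate 2 also reached the edge after quantile normalization (-0.07, percentile 2.5).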

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

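No test in this part was chosen after its result was seen. Probe sets without a gene name lie outside the comparisons of named genes, and 746 of 4721 such probe sets were above the reference level on all 3 arrays (15.8%). None of the 29 non-fly control probe sets was, while 45.6% of the probe sets with 1 gene and 44.5% of those with several were. Which transcripts these 746 probe sets measure was not analysed here, and no explanation was tested.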

How the results depend on the processing

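The reference made of non-fly control probe sets was chosen after seeing the data; all other settings were fixed before. Over 14 settings 4677 to 6043 genes and 99 to 132 transcription factors were above the reference, and leaving out 1 replicate gave 5178 to 5303 genes and 121 to 123 factors. Both lowest counts came without _s_at and _x_at probe sets, where fewer genes were measured. The 99 factors were 36.3% of those measured there, against 40.7% in the main setting. Of the 123 factors, 104 were above in every setting in which they were measured. Quantile normalization and median centring changed the call of no list. With the mean of probe sets the factor share was 37.4%, the wing patterning share 50% and the clock share 75%. The larval cuticle share was 7.69% with the 99th percentile, 23.1% with the median plus 1 and with non-fly controls, 15.4% with the limma trend, and 7.69% to 23.1% without 1 replicate, and its call was lost in the first 4 of these and without replicate 2. The planar polarity share fell to 66.7% (99th percentile) and 73.3% (eggshell and accessory gland genes alone), and both calls were lost. Calls were gained for chitin at 64.3% (99th percentile) and 69.2% (without _s_at and _x_at probe sets). They were gained for clock genes at 87.5% (99th percentile, and eggshell and accessory gland genes alone). For germ line genes they were gained at 9.09% (median plus 1, odorant receptors alone, 3 arrays without a model, non-fly controls). For cell cycle genes they were gained at 0.0% (99th percentile), 6.25% (eggshell and accessory gland genes alone) and 7.14% (without _s_at and _x_at probe sets). Leaving out 1 replicate gave cell cycle calls at 6.25% to 12.5%. The cell cycle share rose to 31.2% (median plus 1, and 3 arrays without a model) and 37.5% (non-fly controls), with no call. The zona pellucida share was 33.3% with the 99th percentile. Single genes fell below the reference without _s_at and _x_at probe sets (Hr39 -0.26, RpL3 -0.78, cnc -3.23, futsch -1.20, bol -4.52). The same was seen with the mean of probe sets (Tsf1 -0.95, br -0.04, cac -0.89, futsch -1.17, kn -0.25, uif -1.68, bol -1.28). There the calls of luna (0.05), mwh (0.09) and tim (0.31) were lost as well. With the 99th percentile fj (-0.02) and dpa (-0.04) fell below the reference. Leaving out 1 replicate ended the calls of CycE (0.56 without replicate 2, 0.63 without replicate 3) and fj (0.51 without replicate 1, 0.54 without replicate 3), and leaving out any 1 ended that of dpa (0.45 to 0.69). Of 337 genes compared one by one 197 were above the reference, 164 of them in every setting in which they were measured. Calls of single genes were gained for 13 genes with non-fly controls, 9 with the median plus 1 and 7 with 3 arrays and no model. Odorant receptors alone gained 5 and the limma trend 4. Calls were lost for 20 genes with the 99th percentile and 16 with eggshell and accessory gland genes alone, although their means stayed over the reference. A further 2 genes, fj and dpa, fell below the reference with the 99th percentile. The deviation of bHLH genes on replicate 2 was -0.014 after median centring, which shifts all genes alike and left the list outside the random range, and that of muscle genes 0.075 over all measured members. The SD of differences between arrays was 1.11 over all named genes and 0.304 to 0.346 without 1 replicate. A different reference level or probe set choice changes the level or the probes by construction. With the median plus 1, however, the adjusted p of the 9 gained calls followed the difference alone, whatever the gene's SD. The weight of a gene's own spread in the limma test thus changed there too. For the other changes the cause was not tested. Signals near the reference limit all calls. No paired analysis was possible because the series holds only 1 group.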

Other observations

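The tests of array scaling and of carried-over muscle were chosen after the result was seen; the test of single probe sets was chosen before its result was seen. The Ets-family repressor gene aop was at 8.13, 7.75 and 10.90 on replicates 1, 2 and 3 (8.93 ± 1.72), and narrowly missed the limma threshold (adjusted p = 0.0526) although all 3 values lay over the reference. It passed without replicate 3 (1.31 over the reference, limma adjusted p = 0.0215), with the limma trend (adjusted p = 0.000399) and after quantile normalization (adjusted p = 0.0428). It also passed with odorant receptors alone (adjusted p = 0.0424), non-fly controls (adjusted p = 0.0024) or the median plus 1 (adjusted p = 3.79e-09) as reference. Among the calls gained with the median plus 1, the adjusted p followed the difference from the reference, whatever the gene's SD. The value of 3.79e-09 therefore does not reflect the spread of aop and is not an effect of the level alone. Of 590 genes above the reference with several probe sets, 306 had another probe set below it on every array; among them were nub, stw, kay, lola, mwh and tkv. The ratio of 3' to 5' control signals was 6.67, 5.65 and 4.76 for actin, 11.2, 7.92 and 9.83 for GAPDH, and 10.7, 8.41 and 9.81 for eIF-4a on replicates 1, 2 and 3. The 3' signal was thus several times the 5' signal for each control on every array. Whether this bias lowered probe sets far from the 3' end was not tested. It limits calls of genes and probe sets as not above the reference.

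Replicate 3 was the highest array for e and for 82 of the 140 genes with an SD over 0.5, and replicate 2 was the lowest for e and for 70 of the 140. The excess of e was 1.99 as deposited and 1.96 after quantile normalization. The deposited arrays already shared a common scale, so this step could change the excess only a little. It shows only that differences in signal distribution left between the deposited arrays do not account for the excess of e. It does not decide on array scaling as a cause. Muscle carried over from the body stays open. The 9 muscle markers above the reference had a median excess of 0.12, below the bound of 0.5 by more than its standard error of 0.25 but by less than the SD of 0.49 over the markers, of which 5 were above 0. The excess was 1.07 for Mlp84B and 0.51 for Act88F but -0.40 for Act79B, so the median over these markers decides nothing. A fault of single probe sets also stays open: only 2 further probe sets of these genes were above the reference, with a median excess of 0.43. A difference in developmental stage between pools staged by eye may contribute as a hypothesis, but it was not tested, and no biological explanation can be drawn from a single group.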
